A study of Mus musculus with 2 samples.

How the data were processed

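H3K36me2, the dimethylated form of lysine 36 of histone H3, was profiled in regulatory T (Treg) cells from mouse spleen, on the C57BL/6 background. There were 2 samples, 1 wild-type library and 1 library from mice with Nsd2 deleted conditionally in Treg cells, so no comparison has a replicate check and no p-value is given for a difference between genotypes. Per the labels' protocols, chromatin was processed with an in situ ChIP library kit and libraries were made with a transposase index kit. The antibody and any input or spike-in control are not given in the sources used here. The submitters' processing notes name Trim Galore, Bowtie2, Picard, HOMER and deepTools, without versions, and the mm10 build.

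The deposited file of each library is a list of regions called by HOMER findPeaks in histone style on that library alone, per the file headers, with no control library in the command. Per the file headers, peaks of 500 bp were stitched into regions of variable length, with a minimum distance between peaks of 1000 bp, a fragment length of 180 bp, at most 1.0 tag considered per bp and an effective genome size of 2000000000 bp. A peak had to pass a Poisson threshold of 0.001 against the genome and of 0.0001 against the surrounding 10000 bp. That threshold came to 13 tags in the wild-type library, which had 17158154 tags, and to 12 tags in the knockout library, which had 14789700 tags. Scaled to 10000000 tags, these are 7.58 and 8.11 tags, so the authors' caller was stricter in the shallower knockout library. The tail probabilities computed from the headers' expected tags per peak were 0.00051 and 0.00045.

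The signal value of each region is the authors' normalised tag count, scaled by HOMER to 10000000 tags per library per the file headers. Multiplied back by library size, 100% of values under 10 came out as multiples of 0.5 tags, with a tolerance of 0.05 on the count of such steps. The score deposited by the authors for each region is on the scale of tags in a 500 bp peak, judged from its values. Long regions can carry a score at the threshold, so the score does not follow total signal there. The clonal fold change, a ratio in the authors' deposited lists, was not used. Scaling to equal tag totals removes any genome-wide change in the amount of the mark, which therefore could not be measured. Tag counts are PCR reads without molecular identifiers, and intervals cover counting error only.

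Region lengths were taken as end minus start, as in the files, and coordinates are printed as deposited. Overlaps were computed with interval code in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) rather than bedtools, with at least 1 bp counted as shared. Chance overlap was described with 100 rotations of the knockout regions around each chromosome. Shares have exact Clopper-Pearson 95% intervals. Ratios of covered length and the Jaccard index (base pairs in both lists over base pairs in either) have 95% intervals from 2000 resamplings of chromosomes 1 to 19 and X, which describe spread over the genome and not over animals.

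Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly named mm10 by the submitters. The table used here gives gene starts and ends without strand or exons. The planned split into promoter, exon and intron could therefore not be made, nor its wider promoter window, and regions were placed inside or outside protein-coding gene bodies. Overlapping genes share regions. For each protein-coding gene on chromosomes 1 to 19 and X, the covered share is the percentage of gene-body base pairs inside regions. Genes of at least 2000 bp with a region in either library were measured. A gene was counted as lower or higher in the knockout when its covered share differed by at least 20 percentage points, a rule of size and not a test.

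The lists of genes, 16 in number with 293 members, all found in the annotation, were fixed before the data were examined, as were the rule for named genes and the main alternatives. The median difference of each list was set beside 10000 random lists of the same size, matched in 5 classes of gene length and 5 classes of mean covered share over both libraries. This percentile describes these 2 libraries. Named by rule were Nsd2, Nsd1, Nsd3, Ash1l, Setd2, Foxp3, Il2ra, Ctla4, Ikzf2 and Cxcr4. The rule added, among genes of at least 10000 bp, the 10 with the largest drop from a wild-type covered share of at least 50% and the 10 with the largest rise to a knockout covered share of at least 50%. It also took the 3 members of each list with the largest difference, the 3 top-scoring regions per library and the 3 longest regions per library without a base in the other. Some genes that the rule picked are not reported here individually and stay in all counts and lists.

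The code was tested on simulated data, with a knockout list made from the wild-type list by removing all regions over 200 seeded genes. Of these genes 200, and none of 432 untouched genes, were counted as lower. Seeded genes lost all their cover and untouched genes kept theirs by construction, so these counts check the code alone. They give no rate of false calls for the rule, because the simulated list held no other change. Alternatives covered the caller threshold, list length, merging of regions up to 5000 bp apart, a minimum length of 1000 bp, autosomes only, stricter overlap, other difference sizes, flanks of 5000 bp, all gene lengths and scaling for covered length. Added after the data were seen were ranking by normalised tag count, a common tag threshold scaled by library size, other list statistics and other classes for the gene-body split. For the common threshold, wild-type regions of 500 bp needed at least 13.9 tags, the knockout threshold scaled to the wild-type library size, and longer regions were kept, so the setting acts on the shortest regions alone. Leaving out replicates was not possible with 1 library per genotype.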

Results

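The data were lists of genomic regions enriched for H3K36me2 in splenic Treg cells, the Foxp3-expressing CD4 T cells that restrain immune responses. NSD2 is a histone methyltransferase that places this mark. The comparison asked how the genomic pattern of H3K36me2 differed between wild-type Treg cells and Treg cells from mice with a Treg-specific Nsd2 deletion. Each genotype was represented by 1 library, of 17158154 tags for wild type and 14789700 tags for the knockout. No difference below therefore has a replicate error, and the intervals describe counting or the spread over chromosomes within these libraries.

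Of the targeted gene and the other H3K36 methyltransferase genes, only Nsd3 had more than 4% of its body inside regions, with 4.76% in wild type and 4.84% in the knockout. Nsd2 (chromosome 5, 33820676 to 33897966) held no wild-type region and 1 knockout region of 500 bp in its 77291 bp body. Regions of a histone mark do not show whether an exon was deleted, so this does not check the genotype labels. Setd2, which encodes the main H3K36 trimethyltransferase, had 0 bp in wild type and 500 bp in the knockout. Nsd1 had 643 bp and 1105 bp, Ash1l 2000 bp and 1188 bp, and Nsd3 5625 bp and 5711 bp. Of the 18 measured members of the list of H3K36 writers, erasers and readers, none differed by 20 percentage points or more.

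The knockout list was shorter and covered less of the genome, while the longest domains were about as numerous. Wild-type Treg cells had 54527 regions over 42.5 Mb and knockout cells 39745 regions over 31.6 Mb. The knockout thus had 72.9% as many regions (95% interval 72.0 to 73.8) and 74.4% of the covered length (71.1 to 77.4 over chromosomes). Mean region length was 780 bp and 796 bp, and the mean normalised tag count, without mitochondrial regions, was 12.6 and 14.0 per region. Regions of at least 4 kb numbered 418 in wild type and 393 in the knockout. Among regions with at least 50 normalised tags, 828 were wild-type and 835 knockout, whereas with at least 20 normalised tags the numbers were 5464 and 4623. With at least 10 and at least 15 normalised tags the knockout had 82.7% (81.04 to 84.4) and 80.3% (77.9 to 82.8) as many regions. The authors' headers put 7.17% of wild-type tags and 5.89% of knockout tags inside regions. When wild-type regions of 500 bp were held to the knockout's tag threshold scaled to the wild-type library size (13.9 tags), an alternative added after the data were seen, the knockout had 104% as many regions (102.7 to 105.6) and 92.2% of the covered length. That total combined 174% of the remaining wild-type regions of 500 bp (170.5 to 178.3) with 70.4% of the longer regions (69.1 to 71.8), which the setting left as they were.

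Sharing of at least 1 bp between the lists went up with region length, as it also does for rotated lists. Of wild-type regions of at least 4 kb, 99.8% (exact binomial 95% interval 98.67 to 99.99) had a base in a knockout region, against 16.1% (15.6 to 16.5) of the 28727 regions of 500 bp. Rotating the knockout regions around the chromosomes gave medians of 9.34% (highest 16.7%) and 2.12% (highest 2.66%) for these classes in 100 rotations. In the other direction the shares were 99.7% (98.59 to 99.99) and 25.7% (25.1 to 26.3). Domains of at least 4 kb covered to at least 80% in both libraries numbered 247. Over all lengths, 29.8% of wild-type regions (29.5 to 30.2) overlapped knockout regions and 41.0% of knockout regions (40.5 to 41.5) overlapped wild-type regions. For the first of these shares the rotations gave a median of 2.57% and a highest value of 3.49%, while knockout regions moved by 10 kb overlapped 12.7% and by 200 kb 6.37% of wild-type regions. The Jaccard index was 20.2% (19.2 to 20.8) against a median of 0.77% for the rotations. Without a replicate of either genotype, the overlap that repeat libraries of the same cells would show is unknown.

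**Figure D1:**
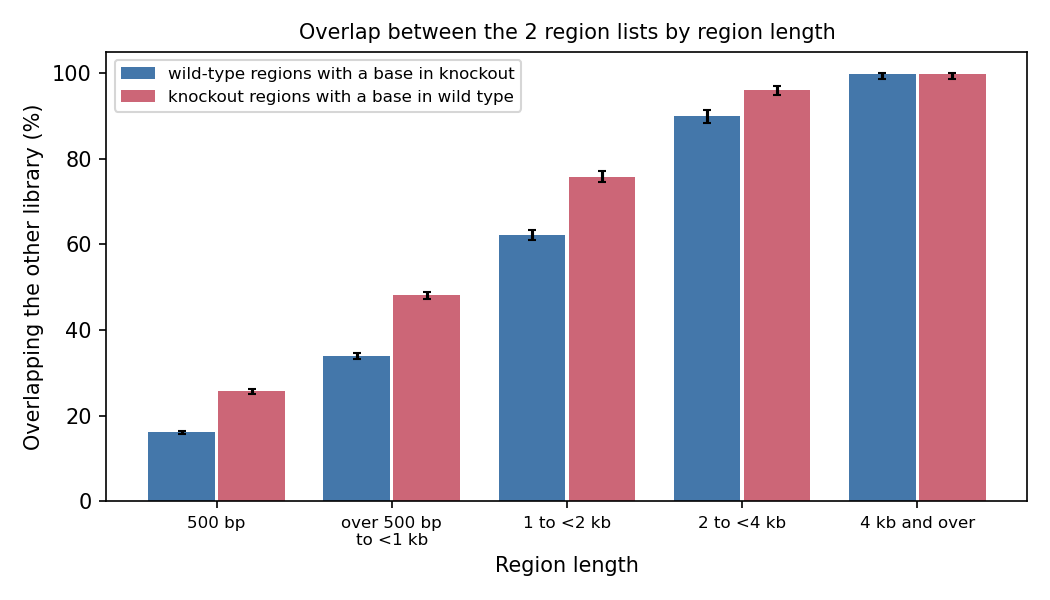
Share of regions of each library (y axis, percent) with at least 1 bp inside a region of the other library, by region length (x axis), with exact binomial 95% intervals as error bars. Overlap goes from 16.1% of wild-type and 25.7% of knockout regions at 500 bp to 99.8% and 99.7% at 4 kb and over.

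Gene bodies held more of the covered base pairs than their share of the genome in both lists. Protein-coding gene bodies made up 39.4% of the annotated chromosome spans and held 61.3% of covered base pairs in wild type and 61.7% in the knockout. The difference of 0.32 percentage points had a 95% interval over chromosomes of -0.40 to 1.004. By number, knockout regions were 73.9% of wild-type regions inside gene bodies and 71.2% outside, a difference of 2.68 points (0.75 to 4.59, counting error). That interval treats regions as independent, and on some chromosomes the percentage was higher outside than inside. By region length, the difference was -6.18 points (-17.5 to 5.04) for regions of at least 2 kb, 3.19 points (0.53 to 5.92) for those of 500 bp, 3.0003 points (-0.29 to 6.19) over 500 bp and under 1 kb, and 2.97 points (-2.86 to 8.65) from 1 to under 2 kb.

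Coverage in the knockout relative to wild type varied with gene length and gene density, in splits chosen after the values were seen. In the 5300 genes of 2 to under 10 kb, the knockout covered 101% of the wild-type length (94.4 to 107 over chromosomes). This went down through 88.2% for genes of 10 to under 30 kb, 76.1% for 30 to under 100 kb and 66.1% for 100 to under 300 kb, to 60.2% (54.5 to 65.5) in the 557 genes of 300 kb and over. At the common tag threshold the same classes ran from 122% to 78.5%, so the order by length stayed while its level moved, with regions over 500 bp left as they were. In the autosomal 1 Mb windows with the fewest coding genes, knockout regions were 61.7% of wild-type regions (57.8 to 65.7), and in the windows with the most they were 84.4% (82.6 to 86.1). The classes between had 65.2%, 62.9% and 69.8%, so the class with the most genes stood apart. At the common tag threshold the end classes had 95.2% (89.1 to 101.7) and 117.7% (115.04 to 120.4). That setting removed only wild-type regions of 500 bp, so a percentage over 100 is not by itself an excess of knockout regions. Among chromosomes the percentage was lowest on chromosome 13, at 57.8% (54.1 to 61.7), and highest on chromosome 11, at 84.6% (80.7 to 88.7). At the common tag threshold chromosome 13 stayed lowest, at 86.1% (80.2 to 92.5). Chromosome 11 was then at 118.9% (112.9 to 125.1), and X was highest, at 123.2% (107.2 to 141.6).

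**Figure D2:**
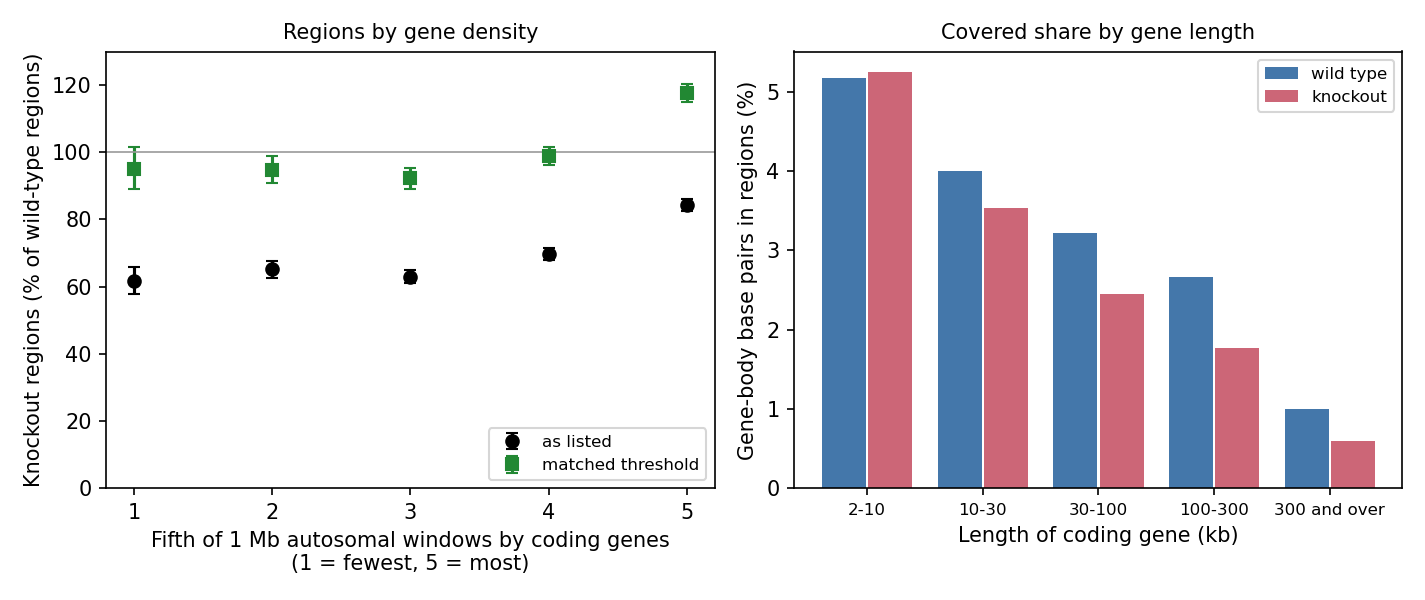
Left, knockout regions as percent of wild-type regions (y axis) in 5 equal classes of autosomal 1 Mb windows ordered by number of coding genes (x axis), for the lists as deposited and at the common tag threshold, with 95% counting intervals. Right, percent of gene-body base pairs inside regions (y axis) by gene length in kb (x axis) in each library; the knockout bar is 101% of the wild-type bar for the shortest class and 60.2% for the longest.

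Genes of pan-T cell identity had the largest covered share of the 16 lists in both genotypes, with 19.3% of their pooled gene bodies inside regions in wild type and 19.3% in the knockout, against 2.53% and 1.89% for all 19190 coding genes of at least 2 kb. All 24 measured members had a region in both libraries, 14 with a larger and 10 with a smaller covered share in the knockout. Cd27, a costimulatory receptor, was covered to 36.7% in wild type and 64.2% in the knockout. Cd3d, a chain of the T cell receptor complex, was covered to 43.3% and 59.9%, and Lat, an adaptor of that receptor, to 13.1% and 31.4%. Bcl11b, a transcription factor of T cell commitment and chosen here after its values were seen, was covered to 61.8% and 58.9%. The list's median difference of 0.63 points lay at the 97.8th percentile of matched random lists. Matching used only 5 classes of covered share, and the list's median wild-type share was 21.4%, against 3.21% for all measured genes. The percentile therefore cannot separate T cell identity from high cover. Under 5 of 12 alternatives the list lay inside their central 95%, and in the higher-scoring 50% of regions the median was -1.49 points.

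Treg signature genes were covered to 10.1% in wild type and 9.13% in the knockout. Of 22 measured members, 9 had a larger share in the knockout, 9 a smaller one, and none differed by 20 points. Foxp3 (chromosome X, 7579676 to 7595243), the lineage-defining transcription factor, held 2743 bp in wild type and 4652 bp in the knockout, a covered share of 17.6% and 29.9%. Across the alternatives that difference ranged from -13.6 to 55.8 points. Il2ra, the high-affinity IL-2 receptor chain, was covered to 13.5% and 15.5%, and Ikzf2, encoding Helios, to 14.4% and 14.95%. Ctla4 held no region in either library. Tgfb1, a suppressive cytokine gene, held 0 bp and 2502 bp, and Ebi3, a subunit of IL-35, 0 bp and 500 bp. The list's median difference was 0 and its mean difference 0.71 points, the median at the 88.4th percentile of random lists.

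Chemokine receptor and homing genes were covered to 13.3% in wild type and 12.6% in the knockout, with 10 of 17 measured members smaller and 7 larger in the knockout. Cxcr4 (chromosome 1, 128588199 to 128592299), the CXCL12 receptor, had 1 wild-type region reaching 425 bp into its body and none in the knockout. With 50 kb on either side, a window chosen after the values were seen, its neighbourhood held 17580 bp in 16 regions in wild type and 11363 bp in 9 regions in the knockout. In the same window, covered length was also lower in the knockout at Nsd1, Nsd3, Setd2 and Il2ra, and higher at Nsd2, Ash1l, Foxp3, Ikzf2 and Ctla4, the last with 2225 bp and 5663 bp. The covered share of Klf2, a transcription factor of T cell trafficking, was 38.9% and 19.5%, that of Ccr6 25.5% and 14.0%, and that of Ccr8, a receptor of activated Treg cells, 76.7% and 87.6%. The list's median difference was -1.71 points, at the 35.1st percentile, and became 1.74 points when knockout shares were divided by the ratio of covered lengths.

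IL-2 and STAT5 signalling genes were covered to 16.1% in wild type and 17.4% in the knockout, with 9 of 14 measured members larger in the knockout. Il2rg, the common gamma chain, was covered to 12.9% and 40.6%, and Socs3, a cytokine signalling inhibitor, to 29.9% and 57.3%. Cish, another such inhibitor, was covered to 55.3% and 39.7%. The list's median difference was 3.25 points, at the 96.4th percentile, and outside the central 95% of random lists under 3 of 12 alternatives (percentiles from 57.03 to 98.7). Among T cell receptor, NF-kB and NFAT genes, covered to 11.4% and 10.4%, 12 of 20 measured members were smaller in the knockout. Nfkb2, an NF-kB subunit, was covered to 4.38% and 35.005%, Egr1 to 0% and 24.6%, and Tnfaip3, an NF-kB inhibitor, to 33.2% and 21.1%. Genes of the effector T cell lineages had 6.49% and 4.62% of their bodies covered. Zbtb7b, encoding ThPOK, was covered to 67.8% and 49.4% and Tnf to 41.3% and 26.4%. Median differences were -0.85 points at the 68.9th percentile for the NF-kB list and -1.31 points at the 52.9th for the effector list. Dividing knockout shares by the covered-length ratio gave 0.54 and -0.34 points, and the mean of the NF-kB list, at 0.66 points, differed in sign from its median.

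Among the other lists, genes of mTOR, glycolysis and mitochondria were covered to 6.80% and 5.77%. Their median difference was 0.26 points at the 97.8th percentile and their mean difference -0.21 points. Under 7 of 12 alternatives this list lay inside the central 95%, with medians of -1.11 points without regions under 1 kb, -0.59 with flanks of 5 kb and -0.0685 in the 50% with the most normalised tags. Ldha was covered to 8.23% and 0%, Tsc2 to 7.18% and 14.6%, and Slc2a1 to 14.8% and 19.95%. Polycomb and H3K27 enzyme genes were covered to 3.59% and 4.03%, with a median difference of -0.30 and a mean of 3.59 points, and with Ring1 at 17.5% and 46.7%, Kdm6b at 19.03% and 36.3% and Cbx8 at 0% and 10.8%. The H3K36 enzymes and readers were covered to 5.05% and 5.18%, and housekeeping genes to 4.98% and 5.61%, with Actb at 67.2% and 37.5%. The median percentiles of these 3 lists were 68.1, 96.0 and 80.1. Genes silent in T cells had little of their bodies inside regions, at 0.72% and 0.42% for developmental regulators and 0.06% in each library for long neuronal and liver genes. Their median percentiles were 43.7 and 82.7. The covered share does not measure the amount of the mark below the calling threshold. Of the list members named so far, Actb turned to at most 33.1 points, Zbtb7b to 29.9, Cish to 22.02, Tnf to 15.5 and Ccr6 to 11.2 points under at least 1 alternative. Ring1 turned to -9.75, Tsc2 to -6.58, Ikzf2 to -4.92, Lat to -1.17, Nsd3 to -3.89, Slc2a1 to -1.14 and Il2ra to -0.98 points, and Ash1l to 0.53 points. The differences of Il2rg, Socs3, Egr1, Klf2, Cd3d, Ebi3, Cbx8, Cxcr4, Ldha, Nsd2 and Setd2 went to 0 under at least 1 alternative, while those of Nfkb2 and Cd27 went down to 16.2 and 15.1 points. A difference of 0 can mean that no region was left, as for Cxcr4 without regions under 1 kb. It can also mean equal cover after merging, as for Socs3. In all, 2 of the 15 lists given a percentile lay outside the central 95% of random lists, where 0.75 would do so by chance.

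Pooled over each list, markers of other cell types were less covered than the lists of T cell genes in both libraries, which need not hold for each marker. B cell genes were covered to 1.76% in wild type and 0.96% in the knockout, with 10 of 14 members holding a region in wild type and 8 in the knockout. Spib was covered to 12.5% and 26.9%, and Fcer2a to 9.16% and 0%. Myeloid and dendritic cell genes were covered to 2.98% and 2.92%, above the 2.53% and 1.89% of all coding genes of at least 2 kb. NK and CD8 T cell genes had 2274 bp in regions in wild type, over 4 of 8 members including Gzma and Cd8b1, and 0 bp in the knockout. Erythroid genes had 761 bp in wild type, all in Klf1, and 0 bp in the knockout, and under 4 alternatives Klf1 held none in either library. The median differences were -0.75 points at the 38.2nd percentile for B cell genes, whose mean was 1.33 points, -0.74 points at the 63.2nd for myeloid genes, whose mean was 0.24 points, and -4.86 points at the 6.93rd for NK and CD8 genes. The last list, with 4 measured members, lay outside the central 95% under 3 of 7 alternatives (percentiles from 0.68 to 10.1), and the differences of Gzma and Cd8b1 went to 0 under at least 1.

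**Figure D3:**
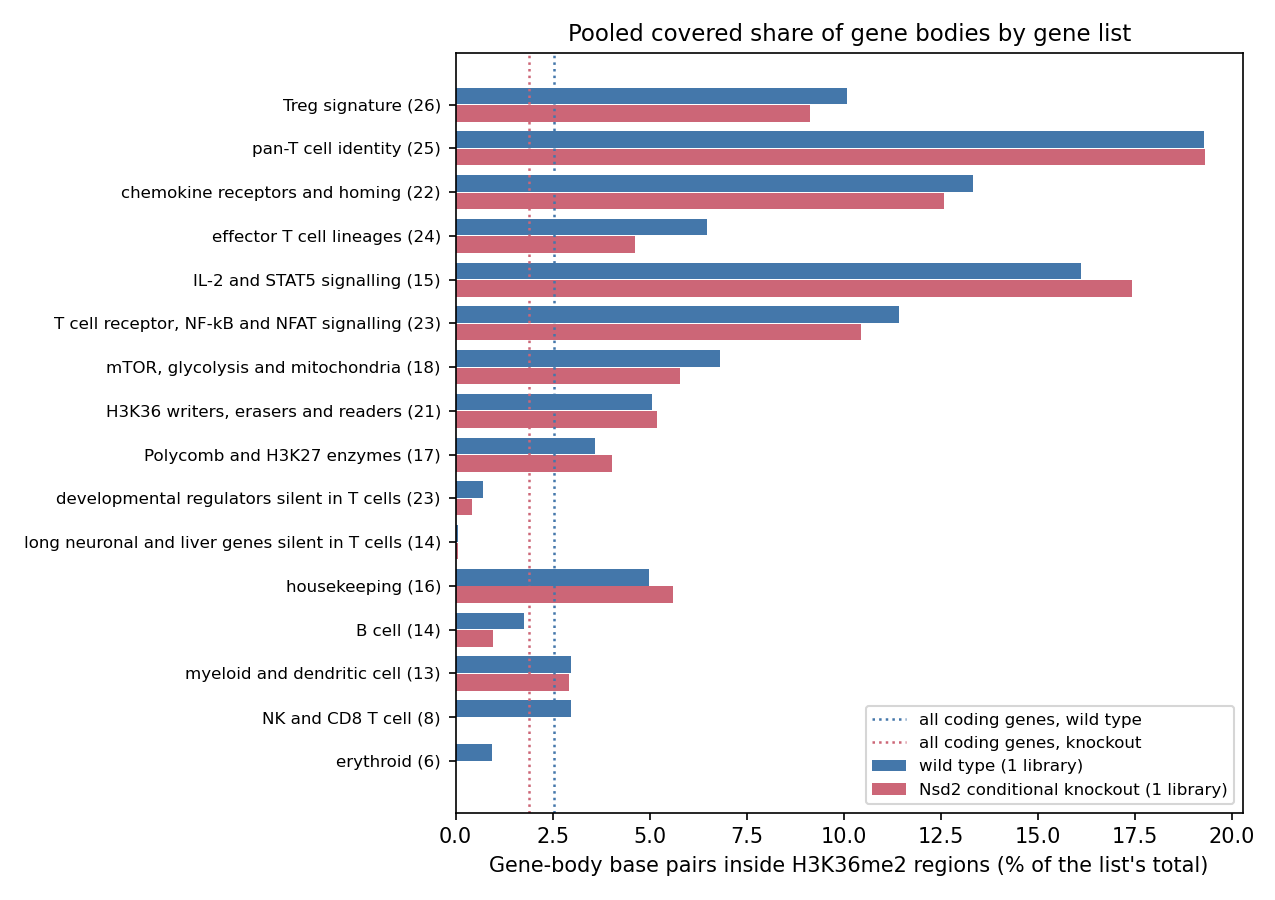
Percent of pooled gene-body base pairs inside H3K36me2 regions (x axis) for each gene list (y axis, number of members of at least 2 kb in brackets) in the wild-type and knockout libraries. Dotted lines mark all coding genes, at 2.53% and 1.89%; pan-T cell genes are at 19.3% in both libraries.

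Across 11217 measured coding genes, individual differences went both ways. In wild type 9481 genes held a region, in the knockout 8664 and in both 6928. The median difference was -0.69 points, and 0.04 points after dividing by the covered-length ratio. In all, 6701 genes had a smaller and 4119 a larger covered share in the knockout, and by at least 20 points 192 were lower and 216 higher. Median lengths of these genes were 4244 bp and 4265 bp, against 29186 bp for all measured genes, and these counts shifted to 148 and 495 after dividing by the covered-length ratio. Among well-covered genes of at least 10 kb, the largest differences toward lower coverage were in Rhog, a small GTPase gene, from 66.7% to 28.2%, and Fam110a, from 57.9% to 28.8%. Lif, a cytokine gene, had 62.8% and 41.6%, Trp53i11 53.3% and 32.5%, and Ptp4a3, a phosphatase gene, 57.6% and 37.0%. The next were Zbtb7b, Neurl3 (68.8% and 52.7%), Ski, an inhibitor of TGF-beta signalling (51.6% and 41.7%), Hemk1 (70.4% and 61.4%) and Nsmce1 (58.4% and 49.7%). Across the gene-level alternatives, Lif and Trp53i11 stayed lower. The others turned under at least 1 alternative, with highest differences of 41.6 points for Neurl3, 29.9 for Zbtb7b, 22.4 for Rhog, 15.7 for Ski, 12.1 for Hemk1, 9.61 for Fam110a, 8.29 for Nsmce1 and 3.25 for Ptp4a3.

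Among genes of at least 10 kb covered to at least 50% in the knockout, the largest differences toward higher coverage were led by Dgat1, a triglyceride synthesis enzyme, at 6.37% in wild type and 50.7% in the knockout. Mnt, a MAX-binding repressor, had 30.1% and 69.8%, Sstr3, a somatostatin receptor, 23.1% and 61.5%, and Pias4, a SUMO ligase, 32.8% and 65.6%. Def6, a guanine nucleotide exchange factor of T cells, had 39.7% and 59.1%, Ssbp4 36.9% and 55.3%, and Sla2, an adaptor that dampens receptor signalling, 39.7% and 56.3%. Bcl9l had 43.5% and 58.5%, and Rac2, a small GTPase of blood cells, 44.6% and 58.9%. Pias4, Def6 and Bcl9l stayed higher in the knockout under each gene-level alternative, with lowest differences of 12.1, 10.4 and 3.24 points. Dgat1 went to 0 where only top-scoring regions were kept. Sstr3 went to 0 only where regions up to 5 kb apart were merged, which left equal cover in both libraries. Sla2 turned to -17.4, Ssbp4 to -13.3, Mnt to -3.34 and Rac2 to -1.13 points.

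**Figure D4:**
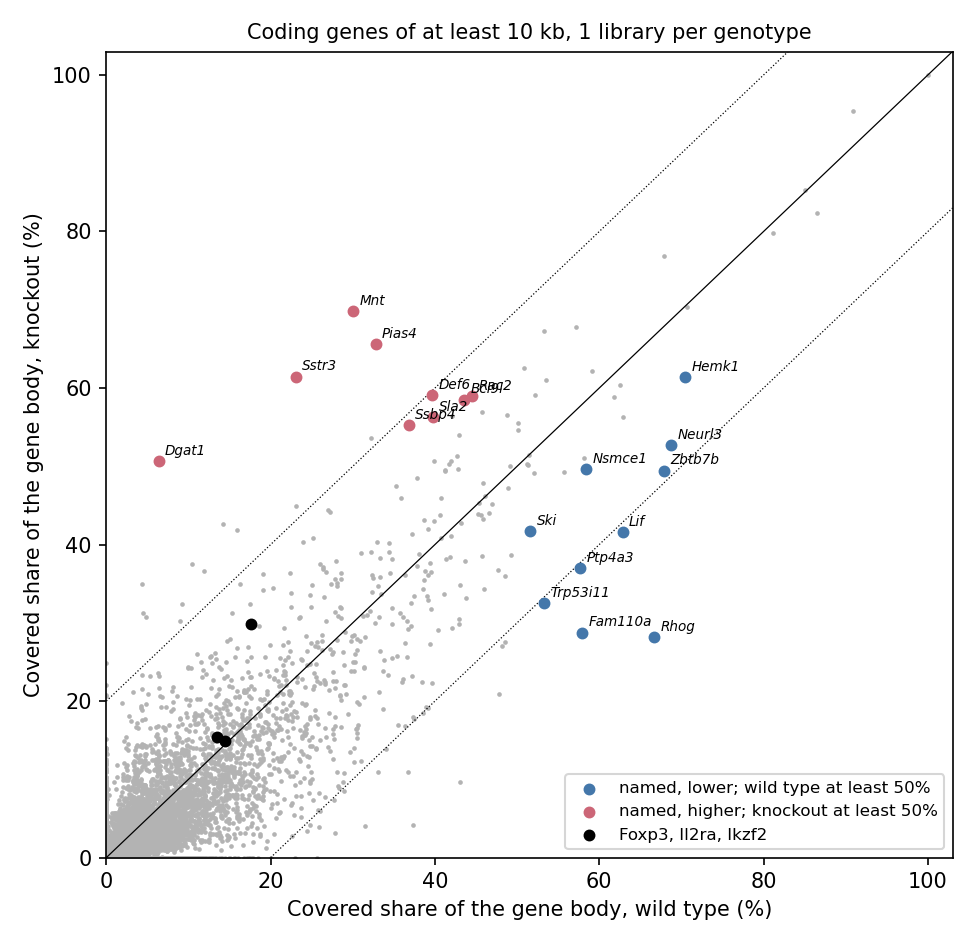
Covered share of the gene body in wild type (x axis, percent) and knockout (y axis, percent) for measured coding genes of at least 10 kb; each point is a gene, the solid line marks equality and dotted lines a difference of 20 points. Coloured points are named genes with the largest differences toward lower coverage from at least 50% in wild type, such as Rhog (66.7% to 28.2%), and toward higher coverage to at least 50% in the knockout, such as Dgat1 (6.37% to 50.7%); black points are Foxp3, Il2ra and Ikzf2.

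The longest wild-type region with no base in a knockout region lay in Nfatc1, encoding a transcription factor of T cell activation (chromosome 18, 80682666 to 80686805, 57.1 normalised tags). The next were 8666 bp from Plxnd1 (chromosome 6, 116004004 to 116007977) and in Rgs12 (chromosome 5, 34972173 to 34975859). The longest knockout region with no base in a wild-type region was at Dgat1 (chromosome 15, 76508986 to 76514228, 81.1 normalised tags). The next were 16568 bp from Cebpb (chromosome 2, 167706999 to 167710425) and 49048 bp from Nkx2-2 (chromosome 2, 147244481 to 147247875). The Nfatc1 region had a score of 13, the wild-type calling threshold. The Dgat1 and Nkx2-2 regions had a score of 12, the knockout threshold. The lack of a call in the other library therefore does not show a lack of signal there. By the authors' score, the top regions of both lists were not at genes of the nuclear gene lists. The highest was a mitochondrial region, with a score of 1087 in wild type and 1064 in the knockout. The others lay on chromosome 2 near 98.67 Mb, over 1 Mb from the nearest coding gene, with scores of 259 and 170.5 in wild type and 220.0 and 180.5 in the knockout. With no control library in the calling, these top-scoring regions cannot be told apart from high background signal.

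**Figure D5:**
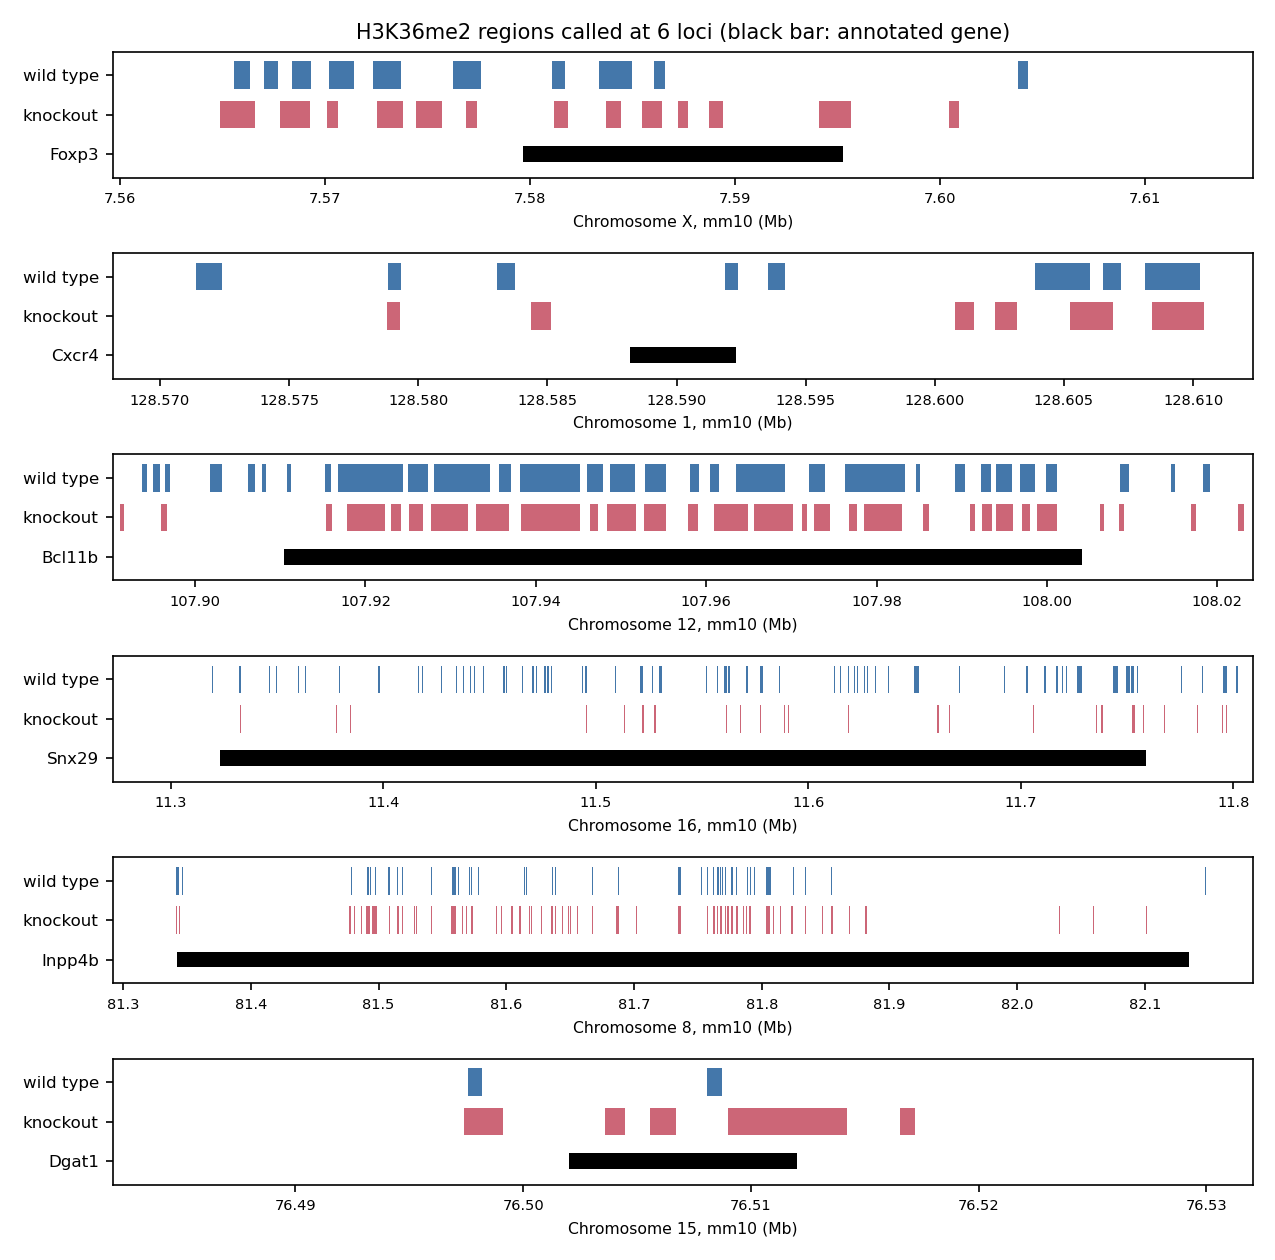
Regions called in wild type and knockout (coloured boxes) along mm10 coordinates in Mb (x axis) at 6 loci, with the annotated gene as a black bar; Bcl11b, Snx29 and Inpp4b were chosen after their values were seen. Bcl11b is covered to 61.8% and 58.9%, Snx29 holds 46401 bp in wild type and 12315 bp in the knockout, and Inpp4b 40375 bp and 68809 bp.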

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

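The tests by gene density, by region length, on the ratio of chromosome percentages, on enrichment of domains, on genes under 5 kb, on genotype and on regions of at least 20 normalised tags were chosen after the result was seen. Signal outside chromosomes 1 to 19 and X, which the gene comparisons did not use, was above the limit that a count of 0 allows. Mitochondrial regions held 29592 normalised tags in wild type and 34481 in the knockout. Regions on unplaced or patch sequences held 8589 normalised tags in wild type and 9826 in the knockout. The Y chromosome carried 8 regions in wild type and 4 in the knockout.

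The first pattern weighed was the lower number of knockout regions, 72.9% of wild type. A higher calling threshold at the lower depth stays open: at the common tag threshold the knockout had 104% as many regions (102.7 to 105.6), but this joined 174% at 500 bp with 70.4% over 500 bp, where borders could not be redrawn without reads, a limit that also holds for the 84.6% (81.3 to 88.0) among regions with at least 20 normalised tags. Uniformly weaker enrichment of the knockout library stays open. It would put fewer normalised tags in domains called in both libraries, which was not seen for domains of at least 4 kb. Without a control library such domains can hold background, so their ratio cannot decide. Normalised tags in mitochondrial regions were also higher in the knockout, at 34481 against 29592 in wild type. The 247 domains of at least 4 kb covered to at least 80% in both libraries had a median knockout to wild-type ratio of normalised tags of 1.07 (1.06 to 1.09), with 179 higher in the knockout. Without that cover as a condition, the 737 merged domains of at least 4 kb gave 1.06 (1.03 to 1.08). These sums count only tags inside each library's own regions, and shorter regions were not tested. Over all regions without mitochondrial ones, the share of library tags was 6.88% in wild type and 5.54% in the knockout, which also moves with what was called. For domains chosen in 1 library the other held less, with ratios of 0.85 (0.82 to 0.87) for the 407 wild-type and 0.76 (0.74 to 0.78) for the 382 knockout domains, a geometric mean of 1.05 (1.03 to 1.08) for knockout over wild type. Loss of Nsd2 stays open, since there was 1 library per genotype.

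The second pattern was that the shortfall in the deposited lists differed along the genome, by 22.7 points (18.3 to 26.9) between the most and the least gene-dense of 5 classes of windows. A different share of near-threshold regions per chromosome stays open: the gap between chromosomes 11 and 13 was 26.9 points as deposited and 32.7 points (24.0 to 41.4) at the common tag threshold, but a gap in points widens by construction when fewer wild-type regions raise each percentage. The ratio of the 2 percentages was 1.47 (1.35 to 1.59) as deposited, 1.38 (1.26 to 1.51) at that threshold and 1.43 (1.30 to 1.57) with it on all regions, and for at least 10, 15 and 20 normalised tags it was 1.40 (1.23 to 1.59), 1.30 (1.07 to 1.59) and 1.51 (1.16 to 1.9596), with 1.21, the square root of the first, inside the last 2 intervals. A library difference that follows base composition cannot be told apart from an effect of Nsd2 loss on gene-poor sequence, because gene density goes with both and no genome sequence was used. Over the 19 autosomes, which are not replicates, the percentage went with coding-gene density (Pearson correlation 0.71, Spearman correlation 0.75, and Pearson correlation 0.56 without the 2 chromosomes farthest from the median density).

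The third pattern was the 216 genes with a covered share at least 20 points higher in the knockout. Stitching of neighbouring peaks stays open. After regions up to 5 kb apart were merged, 75.0% of these genes (68.7 to 80.6) kept the difference. Merging itself raised the number of higher genes from 216 to 812, so a difference kept under it cannot exclude stitching. Small differences in short genes stay open: 30.6% of the genes (24.5 to 37.2) differed by at most 1 kb, but genes over 5 kb cannot do so under the 20-point rule, and among the 128 genes under 5 kb the share was 51.6% (42.6 to 60.5). A difference between single libraries and an effect of genotype both stay open and were not tested.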

How the results depend on the processing

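Tests and settings chosen after the data were seen were the ranking by normalised tag count, the common tag threshold, list means, list members without regions counted at 0, and gene-body splits on regions of 500 bp or with all annotated genes. Across the alternatives, 150 values of list medians stayed on the same side of the central 95% of their random lists and 15 changed side, while 4 values of the pan-T cell and mTOR lists, the lists outside it, changed sign. For the named genes, of list members those that differed by at least 20 points, 284 values stayed within 10 points and 114 moved further, while 9 changed sign among genes that differed by at least 20 points. Sign changes of smaller differences are counted with these. Genes with little or no cover, such as Nsd2, Setd2 and Ctla4, could hardly move by 10 points and add to the 284. Foxp3 and Il2rg lie on X, so with autosomes only their differences were 0 by construction and add to the 114. The erythroid list, with 1 measured member, gave no median. Unless a reason is given, the cause was not tested.

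In the higher-scoring 50% of each list, 22.5% of wild-type and 31.1% of knockout regions overlapped, the Jaccard index was 15.2% and 0 lists lay outside the central 95% of random lists. The pan-T cell median was -1.49 points there, Rhog was at 16.5 and Mnt at -3.34 points. Equal numbers of top-scoring regions gave 98.1% of covered length, overlaps of 24.3% and 24.6%, a Jaccard index of 14.1%, 1 list outside (pan-T cell), Rhog at 16.5 and Actb at 33.1 points. Under both settings the ratio of region numbers is fixed by construction. Merging regions up to 5 kb apart gave 75.5% of regions, 70.9% of covered length, overlaps of 32.4% and 44.2%, a Jaccard index of 28.3%, and 1110 lower and 812 higher genes, with Actb at 32.8 and Ring1 at -9.75 points; merging itself adds the gaps to the covered length. Without regions under 1 kb the values were 74.0% of regions, 78.5% of covered length, overlaps of 39.3% and 53.0%, a Jaccard index of 27.9%, 1 list outside (Polycomb, 4 measured members) and an mTOR median of -1.11 points. The 50% with the most normalised tags gave overlaps of 33.6% and 46.3%, a Jaccard index of 23.7% and an mTOR median of -0.0685 points.

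The common tag threshold on regions of 500 bp gave 104% of regions, 92.2% of covered length, overlaps of 36.6% and 35.6%, a Jaccard index of 21.4% and 1 list outside, the NK and CD8 list of 4 measured members at the 2.27th percentile, with the pan-T cell and mTOR lists inside. Applied to all regions by their score, it removed long wild-type regions whose score was near the threshold, and gave 136% of regions, 129% of covered length, overlaps of 35.1% and 26.3% and a Jaccard index of 17.5%. It then counted 81 lower and 400 higher genes with 0 lists outside, and put Rhog at 22.4, Fam110a at 9.61 and Ptp4a3 at 3.25 points. Requiring 50% of a region to be covered lowered the overlaps to 21.99% and 31.9%, and reciprocal coverage to 17.3% and 23.7%, as a stricter rule must. Flanks of 5 kb left 18 lower and 44 higher genes, by diluting short genes, with an mTOR median of -0.59 points. Scaling by the covered-length ratio gave 148 lower and 495 higher genes, against 192 and 216 without it. By construction a difference of 10 points counted 762 and 619 genes and one of 40 points 21 and 31. With list means, 1 list (pan-T cell) lay outside. On regions of 500 bp, the gene-body share differed by 1.07 points.

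No paired analysis was possible because each genotype had 1 library, which also rules out leaving a replicate out. The wider promoter window was not run, because the annotation used here gives no strand. The lower knockout depth was tested through the common tag threshold alone, which left region borders as they were. By length, the knockout had 75.1% as many regions of 500 bp, 68.8% of those over 500 bp and under 1 kb, 71.1% of those of 1 to under 2 kb, 79.4% of those of 2 to under 4 kb and 94.0% (81.7 to 108.2) of those of 4 kb and over.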

Other observations

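The genes and families in this part were chosen after their values were seen. The coding genes with the most covered base pairs in wild type included Foxp1 (81260 bp, and 71658 bp in the knockout) and Bach2 (75905 and 63227 bp), encoding transcription factors of T cell quiescence. Prkch, a protein kinase C gene, had 62406 and 75399 bp. The largest differences toward less covered length were in long genes: Snx29 had 46401 bp in wild type and 12315 bp in the knockout, Wwox 73889 and 39988 bp, Lpp 39086 and 10971 bp, and Smyd3, which encodes a lysine methyltransferase, 34920 and 8410 bp. The largest difference toward more was in Inpp4b, a phosphoinositide phosphatase gene, with 40375 and 68809 bp. Fyn, a Src-family kinase gene, had 31628 and 40091 bp, and Ets1 41861 and 48882 bp.

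Gene families differed in how much of them was covered. All 8 Gimap genes, GTPases of lymphocyte survival, held a region in both libraries, with 32.0% of pooled gene bodies covered in wild type and 38.9% in the knockout. Genes with H2 symbols, the mouse MHC, were covered to 7.20% and 10.8%, with 12 and 18 of 38 genes holding a region. The 7 Stat genes were covered to 8.45% and 10.2%. Runx genes were covered to 7.53% and 5.79%, and Zfp genes to 1.93% and 1.48%. Dividing knockout shares by the covered-length ratio turned both, to 7.78% and 1.99%. Olfactory receptor genes were nearly free of regions, with 4 of 151 in wild type and 2 in the knockout. No test was run on these families.

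The longest domain of both lists spanned the Ugt1a cluster and Hjurp on chromosome 1 (88211237 to 88270372), with 1829 normalised tags in wild type and 1953 in the knockout. Called without a control library, this stretch cannot be told apart from high background signal.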
